A study of Homo sapiens with 12 samples.

How the data were processed

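H3K9ac chromatin immunoprecipitation sequencing of MOLM-13 cells was compared between 3 DMSO and 3 WM-1119 libraries, grouped and numbered by the sample titles. The submitters' processing notes name Bowtie2, SAMtools, MACS2 and bedtools, without versions or roles, and the build hg38. How regions were merged over libraries and whether duplicate reads were removed is not given in the sources used here. The deposited table gives, per the file headers, 1 column per library. Its values are named TPM by the authors, but the deposited values are CPM, reads scaled to a total of 1000000 over the listed regions: each value is a whole number of reads times 1 step per library, whatever the region's width. In each library 100% of the values of up to 100 reads lay within 0.02 reads of a whole number. For WM-1119 replicate 2 the step lies so near a round value that rounding cannot be ruled out. No count test of treatment used it, while the check for copied libraries did. The table was treated as holding starts counted from 0, and 1 was added to each start. The 6 input samples were not analysed here, so the enrichment over input, the input comparison and the change beyond input were not run.

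The design fixed before the data were examined assumed TPM; the CPM values took the same test. limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust) was fitted to log2(CPM + 1) for regions with a mean of at least 1 CPM, with treatment as the only term, and p-values were adjusted by the Benjamini-Hochberg method. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Genes were placed with the RefSeq gene table of GRCh38.p14, which gives no strand. A region was therefore assigned to a coding gene when it lay within 1 kb of either annotated end, in place of the planned distance to the start, and the region with the highest mean stood for the gene. Of 593 list symbols 592 were matched and 483 had a region before the filter. Exon and intron positions were not used here. The 22 gene lists, fixed in advance, were tested with camera among the regions standing for genes.

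Named regions were, per direction, the 10 with the largest log2 change among those passing the adjusted threshold with non-overlapping groups and a mean at or above the median of tested regions, or the 5 with the smallest p where none passed. In addition 17 genes were named whatever their values, and up to 4 members of each list by their p; the text gives some of these members, chosen after their values were seen. Gene ends were compared with other regions, and the share of CPM in the top 1% of regions between groups, by exact permutation of the 6 libraries. To test the part of background after the calls were seen, the 27 lower regions with the smallest limma p in DMSO and WM-1119 replicates 1 and 2, with a mean of at least 10 CPM, were read in replicate 3 of both groups and set against regions of the same strength on chromosome 8 or elsewhere.

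Alternatives were other pseudocounts (0.1 and 5), no filter or a mean of at least 10 CPM, quantile normalization, median centring, a replicate block, limma without trend and robust, array weights, and leaving out each library. For lists they were an estimated correlation and sums over a gene's regions; fry was run as well, which tests whether a list moves and not whether it differs from other genes. Further settings were chosen after seeing the data. One left out DMSO replicates 1 and 2, which assumes that the lone DMSO library varies like the WM-1119 libraries. One ran edgeR 4.0.16 (quasi-likelihood test, TMM factors) on the recovered reads of 5 libraries, and called 0 regions. One subtracted a background per library and chromosome, the 10th percentile of CPM per bp over regions of over 500 and up to 1200 bp, times the region's width, and rescaled to a common total. It left 63.3%, 66.3% and 85.9% of CPM in the DMSO libraries and 80.8% to 84.5% in the WM-1119 libraries. This was the second estimate tried. The first was the median CPM per bp of regions with a mean below the median region. It left 37.0%, 49.0% and 83.9% in the DMSO libraries and was set aside because it removed so much. Its counts of calls and list results are given beside those of the second. Values of single genes and regions are in places given for the second alone. Background subtraction was also tried with a replicate block and with a mean of at least 10 CPM, and edgeR and the omission of DMSO replicates 1 and 2 with that filter.

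The limma model was tested on simulated data: negative binomial counts with the real means and depths, a dispersion of 0.05 and 200 changed regions among 43838 fitted. It recovered 10% of 2-fold and 86% of 4-fold changes and called 0 unchanged regions. No library was a copy of another: every pair differed by more than sampling noise, with a chi-square per degree of freedom of at least 1.66. Depth ranged 17.7-fold between libraries. 1 read was worth 1.39 CPM in DMSO replicate 1 and 0.0787 CPM in WM-1119 replicate 3, and floors are the value of 3 reads.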

Results

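MOLM-13 is a human acute myeloid leukaemia cell line that carries a KMT2A-MLLT3 fusion and an internal tandem duplication of FLT3. WM-1119 is a small molecule that inhibits the lysine acetyltransferase KAT6A, and the series asks how KAT6A inhibition alters the chromatin of these cells. Acetylated lysine 9 of histone H3 (H3K9ac), a mark of active promoters and enhancers, was profiled by chromatin immunoprecipitation sequencing in 3 libraries from cells given the solvent DMSO and 3 from cells given WM-1119 at 4 µM for 4 days. The series has 12 samples, and the 6 input libraries among them were not analysed here. The table held 47648 regions of the hg38 (GRCh38) genome, with a median width of 401 bp, as CPM, reads scaled to a total of 1000000 over those regions. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

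Depth differed between libraries. The values corresponded to 719329, 1298443 and 7481097 reads in regions for DMSO replicates 1, 2 and 3, and to 4542322, 9996190 and 12705349 for WM-1119 replicates 1, 2 and 3. A count of 0 allowed up to 4.17 CPM in DMSO replicate 1 and up to 0.236 CPM in WM-1119 replicate 3, for counting error only. DMSO replicates 1 and 2 also held more of their reads in weak regions. Regions with a mean below the median region took 8.95% and 7.19% of CPM in these 2 libraries, 2.35% in DMSO replicate 3, and 3.35%, 2.70% and 2.19% in WM-1119 replicates 1, 2 and 3. The first principal component, with 70.9% of the variance, set DMSO replicates 1 and 2 apart from the other 4 libraries. Because CPM is a share of a fixed total, a gain or loss of H3K9ac over the whole genome could not be seen.

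**Figure D1:**
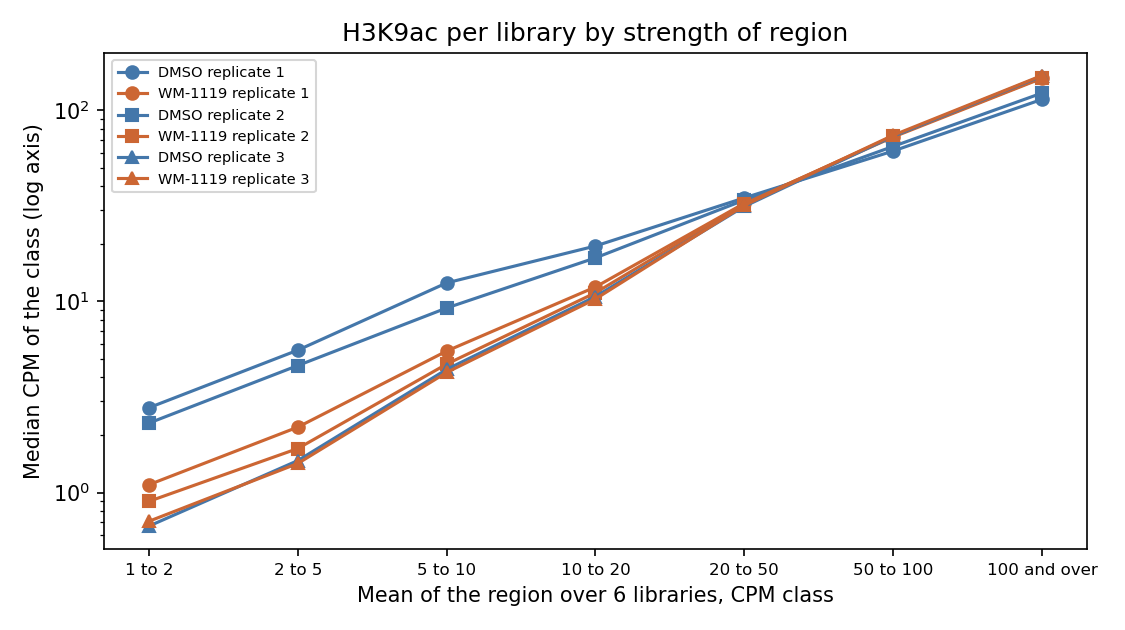
Median CPM per library (vertical log axis) of tested regions grouped by their mean CPM over the 6 libraries (horizontal axis); each line is 1 library. In regions with a mean of 2 to 5 CPM the medians of DMSO replicates 1 and 2 are 5.56 and 4.62 CPM, against 1.47 in DMSO replicate 3 and 1.42 to 2.2 in the WM-1119 libraries.

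H3K9ac fell in 27 regions with WM-1119, and no region rose past the threshold. Most of the 27 lay inside genes and away from their ends. They included parts of the non-coding gene CCDC26 on chromosome 8, the autotaxin gene ENPP2, the long non-coding RNA gene BALR6, PHF10, which encodes a subunit of a SWI/SNF chromatin remodelling complex, and TCF12, which encodes a basic helix-loop-helix transcription factor. The log2 changes ran from -2.16 to -0.76, and in all 27 regions the 3 WM-1119 libraries lay below the 3 DMSO libraries. Of all tested regions 16.9% had non-overlapping groups, where chance gives 10%. The 27 were called by limma among 44763 regions with a mean of at least 1 CPM, on the log2(CPM + 1) scale, which understates the change of weak regions, at a Benjamini-Hochberg adjusted p under 0.05. Without that adjustment, 1153 regions were higher and 4817 lower at p under 0.05, and the median log2 change of all tested regions was -0.47. The count was carried by particular libraries: it was 6, 0 and 19600 without DMSO replicates 1, 2 and 3 and 33, 4 and 5 without WM-1119 replicates 1, 2 and 3. Of the 19600 calls, 2394 were higher and 17206 lower, and beside the 0 there were 398 higher and 1503 lower at an unadjusted p under 0.05. edgeR on the recovered reads of 5 libraries, also chosen after seeing the data, called 0 regions, with 357 higher and 1729 lower at that level, and 4, all lower, among regions with a mean of at least 10 CPM. With DMSO replicates 1 and 2 both left out, an alternative chosen after seeing the data, no region passed in limma, and 1338 were higher and 728 lower at an unadjusted p under 0.05. The 27 regions were all still lower there, as had to follow from groups that do not overlap. Their median log2 change was -0.81, beside a median of 0.06 over all regions. DMSO replicate 3 had helped to call them, so this is no separate support. When a background was subtracted from each library, the number of the 27 that passed depended on how the background was estimated: it was 26 with one estimate and 0 with the other. All 27 were lower with both. Their median log2 change was -1.25 before subtraction and -1.95 and -1.76 after it, with 22 of the 27 at an unadjusted p under 0.05 where none passed. Subtraction took low WM-1119 values towards 0, which enlarges a log2 change. With median centring the median of the 27 was -0.48. Other planned settings changed the count. With a mean of at least 10 CPM 2 regions passed, though all 27 were tested. With quantile normalization 1 passed. For limma without trend and robust 0 did, with 33 higher and 4903 lower at an unadjusted p under 0.05. Other pseudocounts or no filter called 19 to 23, a replicate block 496 and array weights 34995.

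A region of ENPP2 lay at chromosome 8 position 119637334 to 119637978, and its H3K9ac went from 16.9 ± 6.90 CPM in DMSO to 3.54 ± 3.47 CPM in WM-1119 (SD, n = 3 each). Its log2 change was -2.16 ± 0.48 (SE; limma adjusted p = 0.0402). With 1 library left out the change of this region, ENPP2_119637334 by gene and start, ran from -2.75 to -1.71, and it did not pass with the second background estimate subtracted (adjusted p 0.102), with no filter (0.0511) or with pseudocounts of 0.1 and 5 (0.0695 and 0.106), among other settings. A second ENPP2 region at 119643161 to 119644507 changed by -1.32 ± 0.29 (SE). In BALR6, a non-coding gene upstream in coordinate of the chromatin organiser gene SATB1 on chromosome 3, the region at 17979463 to 17981734 went from 44.5 ± 7.94 to 13.6 ± 1.65 CPM (SD, n = 3 each), a log2 change of -1.63 ± 0.25 (SE; limma adjusted p = 0.000174). A neighbouring BALR6 region at 17983354 to 17984920 changed by -1.38 ± 0.29 (SE). Inside TCF12, at chromosome 15 position 56985392 to 56986990, the signal went from 22.1 ± 5.02 to 6.22 ± 1.32 CPM (SD, n = 3 each), a log2 change of -1.67 ± 0.36 (SE). The PHF10 region at chromosome 6 position 169706842 to 169708492 changed by -1.47 ± 0.28 (SE), and that in TBC1D2B at chromosome 15 position 78048710 to 78051118 by -1.45 ± 0.29 (SE). LINC01837, a non-coding gene on chromosome 19, changed by -2.12 ± 0.44 (SE) at 32063584 to 32064562. The remaining named regions overlapped no annotated gene. A region 117746 bp from TOX, the gene of an HMG-box transcription factor, at chromosome 8 position 59236893 to 59237785, had a log2 change of -1.68 ± 0.37 (SE). A region 435084 bp from BTBD3, at chromosome 20 position 11454264 to 11455733, had one of -1.76 ± 0.32 (SE).

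**Figure D2:**
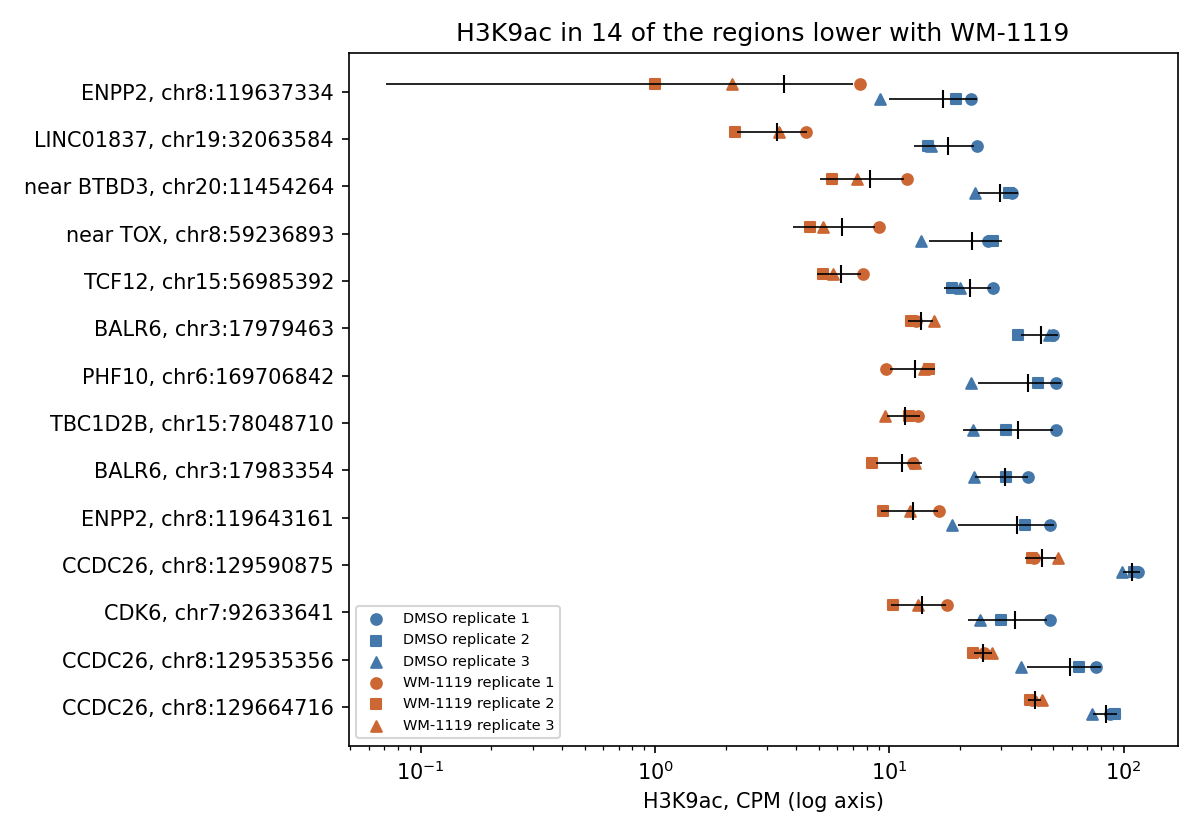
H3K9ac in CPM (horizontal log axis) in the 10 named regions, the 3 regions of CCDC26 and the region inside CDK6, each row labelled by gene, chromosome and start. Coloured symbols are single libraries and black marks are means with SD over 3 libraries; the 3 WM-1119 libraries lie below the 3 DMSO libraries in each row.

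The smallest p belonged to a region of CCDC26, a long non-coding RNA gene in a part of chromosome 8 where blood cells have distal enhancers of MYC. This gene and the region inside CDK6 described below were singled out after their values were seen. The CCDC26 region at chromosome 8 position 129590875 to 129594133, 1848 kb beyond the end of MYC, held 108 ± 8.96 CPM in DMSO and 44.8 ± 6.76 CPM in WM-1119 (SD, n = 3 each). The log2 change was -1.26 ± 0.18 (SE; limma adjusted p = 4.29e-05). The regions at 129664716 to 129667390 and at 129535356 to 129537356 changed by -0.99 ± 0.19 and -1.14 ± 0.22 (SE). CCDC26 held 24 regions, of which 8 had a mean of at least 10 CPM. All 8 were lower in WM-1119 and 7 had an unadjusted limma p under 0.05, but only 3 passed after adjustment. The strongest, at 129545431 to 129550658, had a log2 change of -0.15 with an adjusted p of 0.533. With DMSO replicate 3 alone as the control, 7 of the 8 were lower, with a median log2 change of -0.49. That library had helped to call 3 of them, so this is no separate support. Chromosome 8 regions were lower as a set with all libraries. The 282 with a mean of 20 to 100 CPM had a median log2 change of -0.34 (quartiles -0.67 and -0.04).

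**Figure D3:**
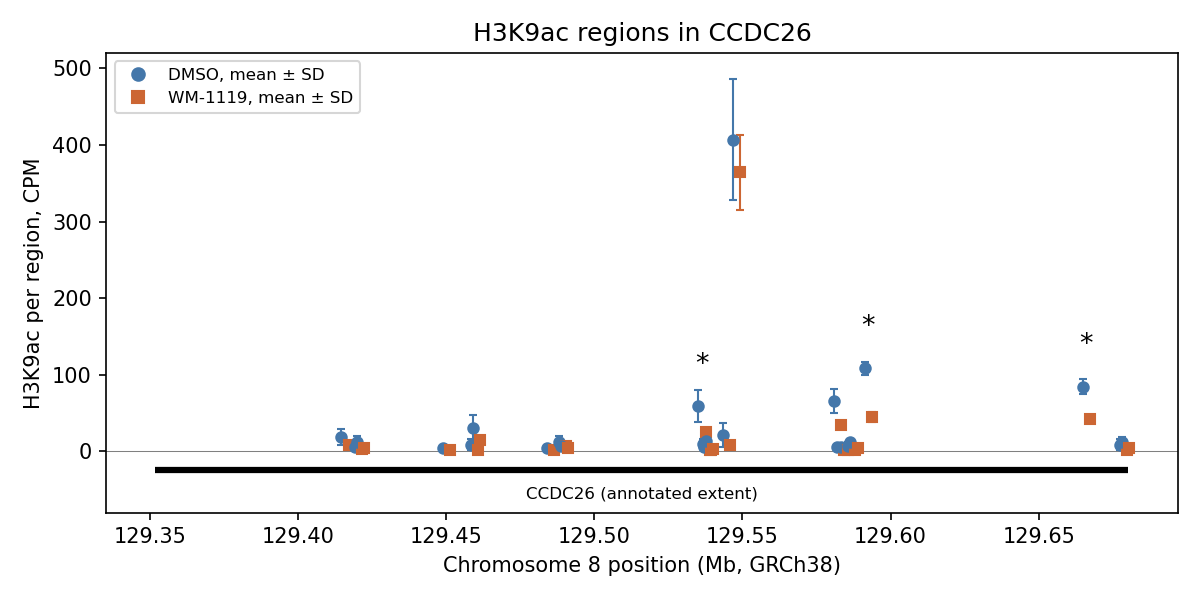
H3K9ac per region in CPM (vertical axis, mean with SD over 3 libraries) along chromosome 8 in Mb (horizontal axis), with DMSO and WM-1119 drawn side by side for each of the 24 regions in CCDC26 and the gene's annotated extent as a bar. Stars mark the 3 regions that passed the adjusted threshold; the strongest region did not.

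Inside CDK6, the gene of a cell cycle kinase, a region at chromosome 7 position 92633641 to 92635696 went from 34.4 ± 12.7 to 13.8 ± 3.63 CPM (SD, n = 3 each), with a limma adjusted p of 0.0498. ELF1, RREB1, RNASEH2B, SENP6, CDKAL1, WIPF1, TTC7A, NDRG1, SNX30, CLEC2D and the non-coding LOC101927588, named after their values were seen, each held 1 of the 27 regions, and ENPP2 and PHF10 each held 1 besides those given above. Of the 27 regions, 23 lay within a gene and away from the ends of coding genes, 2 lay within 1 kb of a coding gene's end (the PHF10 region at 169706842, near the end of its neighbour C6orf120, and that of CLEC2D), and 2 overlapped no gene. Chromosome 8 held 9 of the 27, and 5.49% of the tested regions with a mean of at least 10 CPM. The background of DMSO replicates 1 and 2 on that chromosome was 20.5 and 17.0 CPM per kb, against 5.24 to 8.30 in the other 4 libraries. In those 4 the genome-wide background was 3.36 to 4.38 CPM per kb, so chromosome 8 was raised in them as well. Chromosomes 6, 8, 13 and 19 together held 17 of the 27, and 22.2% of such regions. On chromosomes 6, 13 and 19 the background of DMSO replicate 1 was 12.2, 12.6 and 10.6 CPM per kb, against 8.05 over the genome. That of DMSO replicate 2 was 10.8, 11.2 and 10.2, against 7.44. Self-tests on simulated data, with changed regions of at least 10 CPM and no background difference, recovered 86% of 4-fold and 10% of 2-fold changes.

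No region passed limma's adjusted threshold in the other direction, with 1153 at an unadjusted p under 0.05 and 357 in edgeR. The 5 regions with the smallest p among those higher in WM-1119 failed the adjustment, with limma adjusted p of 0.125 to 0.213. Without DMSO replicate 3 all 5 passed, with adjusted p of 0.00546 to 0.00973, and with the second background estimate subtracted those at LOC100130992, near CHD7 and at CEBPD passed, at 0.0364, 0.00543 and 0.00637. With the first estimate 0 of the 5 passed (limma adjusted p 0.456 to 0.666). With the second and a mean of at least 10 CPM 0 passed as well (0.417 to 0.492). The 5 included CEBPD, which encodes a myeloid transcription factor, at 473 ± 82.1 CPM in DMSO and 664 ± 72.9 CPM in WM-1119 (SD, n = 3 each). Another lay 25837 bp from CHD7, a chromatin remodeller gene, at 68.9 ± 5.09 and 109 ± 14.1 CPM (SD, n = 3 each). The others lay in GPR160, in MPPE1 and in a non-coding gene, LOC100130992, with log2 changes of 0.73 ± 0.19, 0.66 ± 0.18 and 0.57 ± 0.14 (SE). Without DMSO replicates 1 and 2 these were 0.64, 0.08 and 0.33, with 0.26 at CEBPD and 0.72 near CHD7. The split of calls depended on scaling. With median centring of each library 2 regions passed and both were higher, while quantile normalization left 1 call, lower, and a median log2 change of 0.01.

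None of the 17 genes named in advance passed at its end region. Self-tests on simulated data, without the background difference, recovered 10% of 2-fold changes among regions of at least 10 CPM. Of the 17 genes 12 had such a mean. Without DMSO replicate 3, where 19600 regions passed, 10 of the 17 did: HOXA9 and HOXA10, PBX3, MEIS1, CDK6 and KAT6A higher and CDKN1A, ITGAM, MPO and CD14 lower, with adjusted p of 0.00679 to 0.0421. With array weights 13 passed, and with the second background estimate and a replicate block KAT6A and PBX3 did. With 1 library left out the log2 change of HOXA9 ran from 0.09 to 0.42 and that of CDKN1A from -1.70 to -0.74. The HOXA9 and HOXA10 genes, homeobox genes that KMT2A fusions keep active, share 1 region of chromosome 7 at 27148006 to 27175073. It held 959 ± 214 CPM in DMSO and 1137 ± 154 CPM in WM-1119 (SD, n = 3 each), a log2 change of 0.26 ± 0.13 (SE; limma adjusted p = 0.375) that turned to -0.04 with quantile normalization. Their cofactor genes MEIS1 and PBX3 held 666 ± 163 and 641 ± 109 CPM in DMSO and 708 ± 63.9 and 812 ± 112 CPM in WM-1119 (SD, n = 3 each). The MEIS1 difference changed sign with quantile normalization, to -0.06, and that of PBX3 did not. For MYC, MYB, FLT3, BCL2 and the end region of CDK6 the log2 changes were -0.18 ± 0.15, 0.10 ± 0.23, -0.09 ± 0.17, -0.10 ± 0.16 and 0.15 ± 0.14 (SE). None passed, and each changed sign with a scaling alternative: MYC to 0.59, FLT3 to 0.68 and BCL2 to 0.67 with median centring, MYB and CDK6 to -0.07 with quantile normalization. Median centring moved every log2 change up by the same amount, so it turns any small negative change. Without DMSO replicates 1 and 2 FLT3 was at -0.64 ± 0.13, BCL2 at -0.48 ± 0.15 and MYC at -0.58 ± 0.17 (log2 change, SE), and none passed. KAT6A itself had 134 ± 20.4 CPM in DMSO and 166 ± 18.1 CPM in WM-1119 (SD, n = 3 each; limma adjusted p = 0.376).

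None of the myeloid genes named in advance passed. LYZ, the lysozyme gene, held 68.8 ± 24.2 CPM in DMSO and 90.1 ± 24.3 CPM in WM-1119 (SD, n = 3 each; limma adjusted p = 0.39). With 1 library left out its log2 change ran from 0.09 to 0.61. ITGAM and CSF1R were near the floor, with means of 3.78 and 4.01 CPM in DMSO and 1.54 and 2.18 CPM in WM-1119. CD14, CEBPE, MPO and CDKN1A, the gene of the cell cycle inhibitor p21, had DMSO means of 8.77, 15.8, 12.6 and 14.5 CPM and WM-1119 means of 5.49, 11.2, 6.54 and 4.54 CPM. Their limma adjusted p ran from 0.329 for CDKN1A to 0.633 for CD14. With median centring, which moved every log2 change up by the same amount, ITGAM, CSF1R, CD14 and CEBPE changed sign, to 0.06, 0.23, 0.38 and 0.38. MPO and CDKN1A, with larger falls, did not. In these weak regions DMSO replicates 1 and 2 were higher than DMSO replicate 3: CDKN1A had 26.4 and 10.8 CPM in the first 2 and 6.28 in the third.

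Of 22 gene lists, 4 stood apart from other genes in camera's test with a preset correlation of 0.01. With an estimated correlation all 4 calls were lost (camera adjusted p = 0.812 for each). fry, which asks whether a list's own regions moved and does not compare them with other genes, called 0 of the 22 lists. Genes of KAT6 complexes and other lysine acetyltransferases were higher relative to other genes (camera adjusted p = 0.0365), with 22 of 23 regions higher and a median log2 change of 0.25, 6 of them at an unadjusted p under 0.05, and 1 adjusted over the list alone. Constitutively used genes were much the same, at 21 of 23 and 0.24, as were acetyl-lysine readers with 24 of 27 higher and deacetylases with 21 of 24; all regions with a mean of 50 to 100 CPM and of 100 or more had medians of 0.16 and 0.23. BRPF1, a scaffold of the KAT6 complex, went from 118 ± 31.1 to 166 ± 6.20 CPM, and the acetyltransferase gene EP300 from 208 ± 42.7 to 269 ± 10.3 CPM (SD, n = 3 each); both failed over all regions. Interferon response genes (camera adjusted p = 0.00142), lymphoid markers (0.00591) and monocyte and macrophage genes (0.0365) were lower relative to other genes, with 20 of 27, 8 of 11 and 17 of 29 regions lower and 0 passing over the list alone in each. Weak regions were lower in general: all regions with a mean of 2 to 5 and of 10 to 20 CPM had median log2 changes of -0.75 and -0.40, while the lymphoid and interferon lists, with median region means of 2.38 and 13.1 CPM, had medians of -0.26 and -0.21. Against regions standing for other genes of the same strength, a comparison chosen after seeing the data and not tested, the median differences were -0.13, -0.14 and -0.07 for the interferon, lymphoid and monocyte lists and 0.09 for the KAT6 list. For the lymphoid list the direction depended on the summary. In it 7 of 11 regions lay below the same-strength median, yet its median of -0.26 lay above the -0.48 of those medians. Examples were OAS2 at 4.03 ± 1.45 and 1.66 ± 1.63 CPM, CD79A at 18.9 ± 9.47 and 10.5 ± 1.85 CPM, and the chemokine receptor gene CCR2 at 88.7 ± 22.7 and 54.6 ± 19.8 CPM in DMSO and WM-1119 (SD, n = 3 each). The log2 changes of CD79A and CCR2 turned to 0.08 and 0.04 with median centring, which moved every region alike and does not test these genes. Members also went the other way, such as IFIH1 at 49.8 ± 7.37 and 63.3 ± 6.10 CPM and TLR4 at 20.2 ± 6.06 and 30.8 ± 3.72 CPM (SD, n = 3 each). Without DMSO replicate 1 the adjusted p of the interferon and monocyte lists was 0.273, and without DMSO replicate 2 the KAT6 list had 0.232; the number of lists called ran from 2 without DMSO replicate 2 to 8 without DMSO replicate 3, and was 7 without WM-1119 replicate 1. Without DMSO replicates 1 and 2, the libraries with more signal in weak regions, all 4 lists changed direction, with adjusted p of 0.61, 0.0549, 0.945 and 0.325 in the order given.

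The other 18 lists did not pass, with camera adjusted p of 0.0676 for progenitor genes, for acetyl-lysine readers with DOT1L and the super elongation complex, and for lysosome and phagosome genes, 0.0706 for erythroid and megakaryocyte markers and 0.0721 for constitutively used genes. It was 0.192 for proliferation, 0.307 for deacetylases and corepressors, 0.369 for non-blood lineage markers, 0.418 for granulocyte genes, for immediate early genes and for apoptosis, and 0.454 for MHC class II. It was 0.644 for cell cycle arrest and for MAPK and RTK signalling, 0.704 for MYC and ribosome biogenesis, for cytosolic ribosomal proteins and for NF-kB, and 0.892 for the HOXA cluster and KMT2A fusion targets. List tests read only the strongest region near a gene's ends. CDK6 and SENP6, members of the HOXA and KMT2A fusion list, each held a region called lower away from gene ends, which these tests did not read. The test's direction was down, relative to other genes, while the list's own median was above 0 for the HOXA, progenitor, granulocyte, ribosomal protein, NF-kB, MHC class II and MAPK lists; the mean was below 0 for the progenitor, granulocyte, NF-kB and MHC class II lists. Of these 18 lists, 11 passed in at least 1 other setting, counting those chosen after seeing the data. The cytosolic ribosomal protein list did so down relative to other genes with quantile normalization (camera adjusted p = 4.09e-06), without DMSO replicate 1 (0.000472) and without DMSO replicates 1 and 2 (5.6e-17), and up without DMSO replicate 3 (0.0435). Without DMSO replicates 1 and 2 the HOXA and KMT2A fusion list (0.0178) and the MYC list (2.83e-05) were down and the immediate early (0.0183) and NF-kB (0.00118) lists up. Without DMSO replicate 1 the MYC (0.0227) and progenitor (0.0383) lists were down and the immediate early and lysosome lists up (0.0227 for each). Without DMSO replicate 3 the reader (0.0168) and constitutively used (0.0142) lists were up and the erythroid list down (0.0435). Without WM-1119 replicate 1 the proliferation (0.0343) and constitutively used (0.0426) lists were up and the progenitor (0.0221) and erythroid (0.0343) lists down. The genes below were chosen from those with the smallest p in each list after their values were seen. CTSG, the neutrophil protease cathepsin G, went from 38.7 ± 12.7 to 17.4 ± 3.20 CPM, and ANGPT1, a ligand of the TIE2 receptor, from 42.8 ± 14 to 19.3 ± 8.37 CPM (SD, n = 3 each). Both passed when adjusted over the list alone and failed over all regions, with limma adjusted p of 0.0665 and 0.0627. With the second background estimate subtracted both passed over all regions, CTSG at -2.02 ± 0.45 and ANGPT1 at -1.49 ± 0.37 (log2 change, SE; adjusted p 0.00679 and 0.0288), as did CDKN2C (0.00679), EEF1A1 (0.0364) and CCR2 (0.0104). With the first estimate 1 region passed in all, higher with WM-1119, and with the second and a mean of at least 10 CPM 0 did. CDKN2C, the gene of a CDK4 and CDK6 inhibitor, and JUND likewise passed over the list alone, with log2 changes of 0.48 ± 0.13 and 0.46 ± 0.14 (SE), as did CEBPD. Among the constitutively used genes 4 regions passed over the list alone, with B2M at 0.51 ± 0.16, EEF1A1 at 0.46 ± 0.14, GPI at -0.81 ± 0.29 (log2 change, SE) and VCP at 0.46. CTSZ at 0.50 ± 0.16 and CISH at -0.40 ± 0.15 did not; CISH turned to 0.37 with median centring.

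Regions at the ends of coding genes were compared with regions elsewhere. The median log2 change was 0.05 over 13112 regions within 1 kb of a gene's end and -0.62 over 31651 others, a difference of 0.67 (exact permutation p = 0.3, two-sided; 20 assignments of the labels cannot go below 0.1). The gene-end regions were stronger, with a median mean of 39.0 CPM against 2.85. With DMSO replicate 3 as the only control the difference was -0.035. The top 1% of regions took 13.9% ± 2.70 of CPM in DMSO and 16.0% ± 0.71 in WM-1119 (SD, n = 3 each; exact permutation p = 0.4, two-sided). Single libraries ran from 11.6% and 13.3% in DMSO replicates 1 and 2 to 16.9% in DMSO replicate 3. Without DMSO replicates 1 and 2 the difference, 2.10 percentage points over all libraries, was -0.852.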

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

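The settings that subtract a background, leave out DMSO replicates 1 and 2, or use edgeR were chosen after seeing the data. The cause of a difference between settings was not tested, except that fewer libraries leave fewer degrees of freedom. The 27 calls became 2 with a mean of at least 10 CPM, 1 with quantile normalization, 2 with median centring (both higher), 0 for limma without trend and robust (33 higher and 4903 lower at an unadjusted p under 0.05), 34995 with array weights (6337 higher, 28658 lower), and 0 to 19600 with 1 library left out. The filter at a mean of 10 CPM removed none of the 27. They were tested there among 14323 regions with the same median log2 change of -1.25, so only limma's p-values differed. Pseudocounts of 0.1 and 5 and no filter gave 21, 19 and 23, all lower. Background subtraction gave 92 calls (31 higher, 61 lower) with the second estimate and 1, higher, with the first; the second gave 489 with the replicate block and 0 with a mean of at least 10 CPM (722 higher and 490 lower unadjusted). Leaving out DMSO replicates 1 and 2 gave 0 (1338 and 728 unadjusted), and 0 with a mean of at least 10 CPM (452 and 383). edgeR gave 0 (357 and 1729), and 4 with a mean of at least 10 CPM. The 14 regions described individually as lower kept their direction in all 314 values, from -3.77 to -0.22, of which 129 passed the threshold. They came from calls whose groups did not overlap. Settings that only leave out or weight libraries, or change the pseudocount or filter, could therefore not turn their direction.

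With the replicate block 496 regions passed (112 higher, 384 lower) and 5 lists. The labels give same-numbered samples only a shared number. Deviations of same-numbered libraries correlated over regions at 0.22, 0.05 and 0.33. For each WM-1119 library this was its highest value with any DMSO library. Differently numbered libraries ran from -0.27 to 0.06, the highest being DMSO replicate 2 with WM-1119 replicate 1. Whether replicates were paired is open.

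The 4 lists called became 0 with an estimated correlation, 1 with quantile normalization (cytosolic ribosomal proteins, none of the 4, adjusted p 4.09e-06), 1 with the first background estimate (the same list, 1.26e-07) and 2 to 8 with 1 library left out. fry, a test of whether a list's own regions moved and not of a difference from other genes, called 0. In the order KAT6, interferon, lymphoid and monocyte, the adjusted p was 0.812 for each with an estimated correlation, and 0.218, 0.317, 0.435 and 0.317 with quantile normalization; fry's, for its own question, was 0.422, 0.768, 0.546 and 0.772. It was 0.0637 for KAT6 with sums over a gene's regions and, with the second background estimate, 0.113, 0.00508, 0.0108 and 0.113; with the first it was 0.805, 0.237, 0.237 and 0.909. All 4 kept their direction relative to other genes with both estimates. With 1 library left out it ran from 0.00706 to 0.232, 1.18e-05 to 0.273, 0.00219 to 0.043 and 0.00706 to 0.273. Without DMSO replicates 1 and 2 all 4 turned direction, at 0.61, 0.0549, 0.945 and 0.325, and 5 other lists passed. There the difference between gene ends and other regions turned to -0.035, from 0.673, and that of the top 1% share to -0.852 percentage points, from 2.10; the latter was -0.33 with the first background estimate. With 1 library left out these ranged from 0.434 to 1.05 and from 0.93 to 3.58.

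Of 865 values of genes and regions that did not pass, 55 changed sign and 104 passed the threshold. The 5 regions with the smallest p among those higher passed with the replicate block, at adjusted p of 0.00375 to 0.0116. Without DMSO replicates 1 and 2 the log2 changes were HOXA9 and HOXA10 -0.06, CDK6 -0.23, MEIS1 -0.26, MYB -0.34, CEBPE 0.05, CSF1R 0.08, BLK 0.19, ITGAM 0.63 and CD14 0.81; those with a mean of at least 10 CPM among them had the same values with that filter. With edgeR they were CISH 0.03, MYC 0.12, FLT3 0.22, CD14 0.23 and BCL2 0.26, and MYB -0.02 with the filter; with array weights FLT3 0.13. With median centring, which moved all regions alike, they were CCR2 0.04, ITGAM 0.06, CD79A 0.08, CSF1R 0.23, CISH 0.37, CD14 0.38, CEBPE 0.38, MYC 0.59, BCL2 0.67 and FLT3 0.68. With quantile normalization they were HOXA9 and HOXA10 -0.04, MEIS1 -0.06, CDK6 -0.07, MYB -0.07, CEBPE 0.03, CD14 0.22 and CSF1R 0.22. With the first background estimate they were CD79A 0.06, CD14 0.33, CEBPE 1.60, CDK6 -0.10, MEIS1 -0.12 and MYB -0.16. With 1 library left out CD14 ran from -1 to 0.10, CDK6 from -0.05 to 0.34, MEIS1 from -0.05 to 0.30, MYB from -0.18 to 0.31, MYC from -0.37 to 0.02, BCL2 from -0.26 to 0.09 and FLT3 from -0.26 to 0.19. Depth limited weak regions most: 1 read was 1.39 CPM in DMSO replicate 1. The comparisons with input were not run.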

Other observations

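The regions in this paragraph were picked after their values were seen. With the second estimate of background subtracted, regions not described above passed limma's threshold. Higher with WM-1119 were a TSHZ3 region on chromosome 19 at 31348606 (log2 change 2.34 ± 0.34, SE), ZIC2 on chromosome 13 at 99979527 (1.44 ± 0.26) and KLF5 on chromosome 13 at 73058443 (2.61 ± 0.52). Lower was a MIR222HG region on chromosome X at 45757574 (-1.78 ± 0.34). limma's adjusted p for these ran from 3.82e-07 for TSHZ3 to 0.00111 for KLF5. On the values as deposited the changes were 0.73, 0.55, 0.67 and -0.68 and none passed, and with the first estimate 1 region passed in all. Chromosome 8 held 13 of the 31 higher and 12 of the 61 lower calls of the second estimate. The 1 mitochondrial region in the table held 504.6 and 376.6 CPM in DMSO replicates 1 and 2, 17.6 in DMSO replicate 3, and 85.4, 12.3 and 10.8 in the WM-1119 libraries.

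The tests in the following paragraphs were chosen after the result was seen, except the median of chromosome 8 regions and the drawing down of reads. For the 27 lower regions, the part played by higher background in DMSO replicates 1 and 2 is open. One test, read in 1 library a side, argues against such background as the whole cause in 27 regions chosen without replicate 3. Only 8 of those were among the 27 called, so it does not decide the matter for the called regions. The other settings do not decide it either. With median centring, a planned setting, the median log2 change of the 27 was -0.48, with 26 lower and 6 at an unadjusted p under 0.05. In edgeR it was -0.74, with 11 at that level. Subtracting a background did not shrink the median log2 change of -1.25 (median SE 0.25). It was -1.95 (0.41) with the second estimate, with 26 still called lower. With the first it was -1.76 (0.80), with 0 called and 22 at an unadjusted p under 0.05. Rescaling then raised DMSO replicates 1 and 2 most, and low WM-1119 values went towards 0, as in LINC01837, where all 3 became 0. Both enlarge a log2 change, so these values do not decide the question. In 27 regions chosen with DMSO and WM-1119 replicates 1 and 2 alone, 8 of them among the 27 called, DMSO replicate 3 lay above WM-1119 replicate 3 in 22. Regions matched for strength and for lying on chromosome 8 gave 12 (exact p = 8.04e-05, one-sided). The p-values here count regions as independent, which neighbours are not. They read 1 library a side and so hold no spread between samples. Chromosomes 6, 13 and 19, also with raised background, were not matched for. Of the chosen regions 20 lay on chromosome 8, with 15 above, against 46.6% of all there (exact binomial p = 0.00956, one-sided), and 7 elsewhere, with 7 above (0.00526). The median log2 difference over the chosen regions was -0.35, so background, or the choice of regions by their falls, may still add to the -1.25. For the 9 regions called on chromosome 8, subtraction likewise does not decide whether extra background spread over that chromosome is the whole cause. The 15 of 20 chosen there argue against it for the chosen regions. The median log2 change of the 9, -1.23 (median SE 0.22), became -1.64 (0.33) with the second estimate, with 8 still called. It became -1.70 (0.56) with the first, where the SE grew, none was called and all 9 had an unadjusted p under 0.05. When DMSO replicates 1 and 2 were left out it was -0.79, and 3 of the 9 were among the regions chosen without replicate 3, so a part played by background is open. The median over 282 regions of that chromosome with a mean of 20 to 100 CPM was -0.34 (quartiles -0.67 and -0.04). All tested regions with a mean of 20 to 50 and of 50 to 100 CPM had medians of 0 and 0.16. Regions of chromosome 8 were thus lower as a set, as extra background there would make them. The bound on this median, written in advance, does not decide the matter for the 9, which were called for their large falls. A loss of acetylation in treated cells stays open. Of the 10 splits of the 6 libraries into 3 and 3, 3 called at least 27 regions, too few splits for a share under 0.05. The highest other split, DMSO replicates 1 and 2 with WM-1119 replicate 1, called 860, which points to a structure of the libraries.

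The lower values of weak regions with WM-1119 are consistent with higher background in DMSO replicates 1 and 2: regions with a mean below the median region held 2.35% of CPM in DMSO replicate 3, within the 2.19% to 3.35% of the WM-1119 libraries. The tables argue against lower read depth as the whole cause. Drawing WM-1119 replicate 3 down to 719329 reads moved its median log2 value by 0.24, where DMSO replicate 1 lies 1.54 above it, and 3 deeper libraries drawn to the depth of either shallow one moved by -9.27% to 15.6% of the gap. Less H3K9ac at weak regions in treated cells cannot be told apart from background with 3 libraries a side (exact permutation p = 0.3, two-sided, where 0.1 is the smallest possible).

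For the 4 gene lists that passed, the part played by higher background in DMSO replicates 1 and 2 is open, because the tables point both ways. When these libraries were left out, 0 of the 4 kept their direction. When a background was subtracted, all 4 kept their direction relative to other genes with both estimates, though the monocyte list's own median log2 change went from -0.15 to 0.05 with the second; the interferon and lymphoid lists still passed with the second (adjusted p 0.00508 and 0.0108), and none did with the first (lowest 0.237). Of the 10 splits, 7 called at least 4 lists and the highest other called 15; no share under 0.05 can be had from 10 splits. No biological explanation of the list calls was tested.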
